A study of Mus musculus with 12 samples.

How the data were processed

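Total RNA from the cerebral cortex of 12 mice, 3 weeks old, was prepared with spin columns that include a DNase step and labelled with Cy3 by amplification from a poly-dT primer, with spike-in transcripts added, per the labels' protocols. Arrays were 1-colour Agilent mouse designs with 60-base probes, scanned and read with Agilent Feature Extraction 10.7.3.1, per the file headers. Intensity values in the scanner files are the processed signal of each spot, background-subtracted and detrended within the array by that software, per the file headers, with no scaling between arrays. The mean spot signal and median local background, also intensity, were used for an alternative, per the file headers. The authors' series matrix holds 39570 probes; its log2 scale, its centring of every probe on a median of 0 over the arrays and its direction are not stated and were inferred by comparing each deposited column with its own scanner file over 39414 probes. Within 10 columns the comparison gave r from 0.959 to 0.978 across probes, but 0.224 for control female replicate 1 and 0.218 for BPA male replicate 3, so the step that sets those columns apart stays unknown and is not given in the sources used here. The scanner values of these 2 arrays, used in every fit that kept them, may not be the data behind the authors' columns, and no test here settles whether they are. Column medians of that table lay between −0.03 and 0.02.

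The scanner values were taken as log2 of the processed signal minus each array's 75th percentile. Control spots and spots with an outlier flag were left out, the remaining spots of a probe were averaged, and 26 probe names with no spot left on some array were dropped. Probes well above background on all 3 arrays of at least 1 group were kept, 36368 in all. The probe with the highest mean was taken for each gene name, which gave 25550 genes, 16287 of them bright (mean above −2). Of 55681 probe names, 30413 (54.62%) matched a current symbol through the reference table of gene names, built on GRCm38 and used for names alone; the other probes keep the file's name. Where a named gene had other probes, they went the same way as the one used for 14 of 25 genes in males, 12 of 18 in females, 11 of 18 in the averaged comparison, 11 of 22 in the interaction, 10 of 14 in control sexes and 18 of 26 in exposed sexes. Coordinates are those of the array files, build mm9, counted as the files give them.

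Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; the files were read with the data.table package, version 1.17.8), with 1 mean per group over all 12 arrays and 8 residual degrees of freedom. The comparisons were BPA against vehicle in males, in females and averaged over the sexes, the interaction of BPA and sex, and female minus male among controls and among exposed animals. All tests were two-sided. Adjusted p is by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Probes not well above background on any array of 1 group give only a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of its own signal and the lowest signal among probes above background. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

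Before the data were examined, 39 gene lists were fixed for sex-linked genes, receptors and their targets, neuron and glia types, neighbouring tissues and blood, and stress and housekeeping processes. The 38 lists with 5 or more measured members were tested with limma's camera (preset correlation 0.01, adjusted over the lists of a comparison); Y-linked genes, with 4 of 8 measured, are reported one by one. Lists were also tested with a correlation estimated per list and with fry. For each list, members passing over all genes and adjusted over the list alone were counted. The second adjustment does not correct for the number of lists.

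The rule for named genes was also set before the data were examined. For males and females it takes 12 genes per direction, for the averaged comparison 8 and for the interaction 6. Genes must have a symbol and no overlap between groups, or the same direction in both sexes for the averaged comparison. They are ordered by size among those passing, and filled by smallest p where too few pass. All passing genes are named for the sex differences, 15 sex-linked and receptor genes were chosen whatever their values, and up to 4 members of smallest p are given per passing list. Having a symbol was defined only after the files were seen, as a current reference symbol that is not a LOC name, which 17185 of the tested genes have. Not every gene of the rule is printed, and some results are not reported here.

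The alternatives fixed beforehand were quantile normalisation, normexp background correction (offset 50), no filter, a filter on all 12 arrays, every probe by itself, the authors' processed values, eBayes with trend and robust, array weights, the 2 groups alone, the replicate number as a block, and each array left out. Chosen only after the data were seen were leaving out BPA male replicate 3 and control female replicate 1 together, bright genes alone, and bright genes without BPA male replicate 3. A slide block could not be fitted for the BPA effects, since 0 slides hold both treatments. No array was left out of the main setting.

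The same steps were tested on simulated data made from the real means and spreads of 25550 genes. Noise was drawn gene by gene without correlation between genes. With 200 genes changed in the exposed animals, in the male comparison 28.5% were recovered at a log2 change of 0.5, 70.5% at 1 and 89.5% at 2, and for the averaged comparison 54.5%, 81% and 96.5%. No gene was called in the interaction, where none was changed, and the list test found the 1 shifted list of 38 and no other. The replicate numbers in the labels are not tied to dams, so littermates were treated as separate animals in the main setting. Spread within a group covers animals and arrays together.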

Results

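Gene expression was measured in the cerebral cortex of 3-week-old mice after exposure to bisphenol A (BPA), a plastics monomer that can bind estrogen receptors, through the mother during gestation and lactation. The arrays fell into 4 groups of 3: males and females of dams given BPA, and males and females of dams given the vehicle. Dams of the exposed groups had received 500 µg BPA per kg body weight by mouth each day from embryonic day 0, and control dams the vehicle. Ethanol was at 0.01% in both treatments. There were 3 dams per treatment, and each gave a male and a female pup. Each of the 12 one-colour arrays held 59305 mouse spots, and no spot was saturated.

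Between 64.7% and 68.1% of spots were well above background on 10 of the arrays. The share was 73.5% for control female replicate 1 and 90.5% for BPA male replicate 3. The 75th percentile of the signal lay between 478 and 592 units. Replicates correlated with r from 0.994 to 0.995 in control males, 0.992 to 0.994 in control females, 0.996 to 0.996 in BPA females and 0.982 to 0.996 in BPA males, across probes that are not independent replicates. The first principal component carried 49.0% of the variance and set BPA male replicate 3, at 110, apart from the other arrays, at −24.2 to 13.5. All 6 control arrays were on 1 slide and all 6 BPA arrays on the other. Slide and exposure therefore cannot be told apart in any comparison of BPA with vehicle. The interaction cancels a slide shift that is the same in both sexes, but not one that differs by sex. The number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.117 over the 25550 genes tested. All log2 differences below compare 3 arrays per group unless stated, and every probability for a single gene is limma's.

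**Figure D1:**
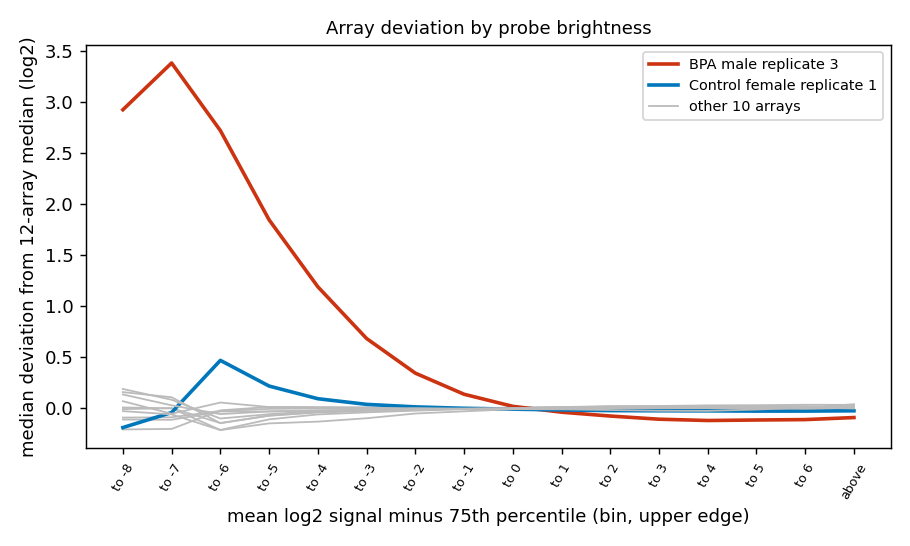
Median log2 deviation of each array from the 12-array median, by probe brightness (mean log2 signal relative to the 75th percentile, in bins), 1 line per array. BPA male replicate 3 (red, 90.5% of spots well above background) lies far above the others among dim probes and slightly below them among bright ones, and control female replicate 1 (blue, 73.5%) deviates by −0.04 in the bin with most probes and by 0.47 in the next brighter bin.

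The comparison of exposed with control males asked which cortical genes differ after BPA in that sex. Gnb4, which encodes a G protein beta subunit (chromosome 3, 32488819 to 32488964), differed by −0.40 (SE 0.06), and Plcb1, a phospholipase C that acts below G protein receptors, was −0.38 (SE 0.07). Tet1, an enzyme that oxidises methylated cytosine in DNA, stood at −0.32 (SE 0.06), and Laptm5, a lysosomal protein of immune cells, at −0.44 (SE 0.08). On the higher side were Dapl1, linked to epithelial differentiation, at 0.97 (SE 0.16), the annexin Anxa8 at 0.81 (SE 0.13), the zinc finger gene Zbtb24, mutated in an immunodeficiency with lost DNA methylation, at 0.36 (SE 0.06), and the oxysterol-binding Osbpl9 at 0.36 (SE 0.07). None of these passed, and each had an adjusted p of 0.463. The remaining genes of smallest p in males had that adjusted p too. They were Clec4a1 (0.43) and Rbm27 (0.34) on the higher side, and Tbc1d16 (−0.53), B3gat2 (−0.44), Gbp3 (−0.55), Apcdd1 (−0.41), Hmgb1 (−0.29), Tasor (−0.30), Senp7 (−0.29) and Bcl7b (−0.29) on the lower side. For a pair of the dimmer genes the sign turned with the scaling: Yy2 was 0.81 in the main setting and −0.33 after quantile normalisation, and Gm13372 was 0.27 and −0.18. The only other probe went the other way for B3gat2 (0.11) and Senp7 (0.09).

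Among 4 further genes of smallest p, the probes were not well above background on any control male array and were on all 3 BPA male arrays. BPA males were at least 1.36-fold higher for Vmn1r219, 1.52-fold for Clca1, 1.89-fold for 4930470P17Rik and 1.91-fold for Nlrp1c-ps, each with an adjusted p of 0.463. These bounds were taken against the lowest signal called above background on each control array, or the gene's own signal where higher, and BPA male replicate 3 raised dim probes in general.

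Over all genes, limma called 0 genes in males. At an unadjusted p under 0.05 there were 2190 genes, 1620 higher and 570 lower, where chance gives 1278. The 3 BPA and 3 control males did not overlap for 11.2% of genes, where chance gives 10%. Single arrays moved the count: without BPA male replicate 1 there was 1 call, LOC634780, and without BPA male replicate 2 there was 1 call, a transcript region on chromosome 2, both higher and named here only after their values were seen. At an unadjusted p under 0.05 there were 3803 genes without BPA male replicate 1 and 1834 without replicate 3.

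As groups, genes of red blood cells, of myelin and of cholesterol synthesis were lower in exposed males under the preset-correlation test (camera). In all, 12 of 38 lists passed, all lower, and each lost its call when the correlation was estimated, with an adjusted p = 0.651 with an estimated correlation. The rotation test fry, which asks whether a list moves one way without comparing it with other genes, passed 0 lists. Erythrocyte genes had a median of −0.78 (11 measured, 10 lower, adjusted p 5.71e-07), with the globins Hbb-bt at −0.92 (SE 0.28) and Hba-a2 at −0.78 (SE 0.23). The median was −0.39 without control male replicate 1 and −0.38 with normexp background correction. Cholesterol and lipid synthesis genes had a median of −0.14 (20 of 24 lower, adjusted p 1.21e-06), with Cyp51 at −0.31; this median was −0.08 without BPA male replicate 2 and −0.23 without BPA male replicate 1. Oligodendrocyte and myelin markers stood at −0.17 (21 of 24 lower, adjusted p 2.21e-05), with Ugt8a at −0.37 and Mag at −0.31; Mbp was at −0.26, but its other 2 probes were at 0.05 and 0.08. Striatal neuron markers were at −0.21 (15 of 18 lower, adjusted p 2.48e-05), microglia and macrophage markers at −0.13 (15 of 19 lower, adjusted p 0.000532) and choroid plexus markers at −0.50 (14 of 15 lower, adjusted p 0.000968). Those 6 lists also passed without BPA male replicate 3, under the preset correlation, but choroid plexus markers did not without BPA male replicate 1 (median −0.11, adjusted p 0.361), nor microglia and macrophage markers without control male replicate 2 (median −0.07, 0.0538). The choroid plexus median was −1.01 without BPA male replicate 2, −0.89 after quantile normalisation and −0.27 with normexp, the microglia one −0.08 with normexp and −0.11 after quantile normalisation, where that list did not pass (adjusted p 0.154), and the striatal one −0.33 without control male replicate 3.

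The other 6 lists did not pass without BPA male replicate 3 or after quantile normalisation, and of them only immediate early genes passed with normexp. Medians with all arrays and without it were −0.20 and −0.30 for activity-regulated immediate early genes (adjusted p 0.00265 and 0.0995), −0.05 and −0.00 for oxidative phosphorylation (0.000174 and 0.711) and −0.05 and −0.01 for cytosolic ribosomal proteins (0.000832 and 0.697). They were −0.05 and −0.03 for oxidative stress and NRF2 genes (0.0193 and 0.518), −0.03 and −0.01 for synaptic vesicle and postsynaptic proteins (0.0229 and 0.851), and −0.06 and −0.03 for heat shock and unfolded protein response genes (0.0369 and 0.764). Other arrays mattered too: the synaptic list had an adjusted p of 0.0874 without control male replicate 1 and 0.201 without control male replicate 3. For heat shock genes it was 0.335 without control male replicate 3 and 0.155 without BPA male replicate 2, and for ribosomal proteins 0.227 without control male replicate 2. Over all genes 0 list members passed, and 10 did when adjusted over the list alone. The 10 were 5 lower erythrocyte genes (Alas2, Hba-a2, Hbb-bt, Hba-a1 and Hbb-b2); Tet1 and Dnmt3a (−0.26), lower, and Mbd1 (0.29) and Dnmt1 (0.26), higher, among enzymes and readers of DNA methylation; and Crh, a stress neuropeptide, at 0.50.

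The comparison of exposed with control females asked the same question in the other sex. Cldn5, the main tight junction protein of brain endothelium (chromosome 16, 18778046 to 18778105), was 0.54 higher in exposed females (SE 0.08), the smallest p of the comparison. Ifit3, an interferon-induced antiviral gene (chromosome 19, 34663105 to 34663164), was at −0.75 (SE 0.12). Higher values were also found for Dph7, which acts in diphthamide synthesis, at 0.41 (SE 0.07), for Scg3, a secretory granule protein of neurons, at 0.29 (SE 0.05), and for the cholesterol exporter Abcg1 at 0.33 (SE 0.07). None passed: the adjusted p was 0.832 for Cldn5 and Ifit3, 0.896 for Dph7 and Scg3, and 1.00 for Abcg1. Others of smallest p were Arfgap2 (0.32), Eif4enif1 (0.31), Sfmbt1 (0.41), Ccdc160 (0.34), Gm7276 (0.49), Dok7 (0.34) and the matrix protease Mmp2 (0.63) on the higher side. On the lower side were 1700001P01Rik (−0.72), G2e3 (−0.40), Lmln (−0.32), Baz1a (−0.48), Tet1 (−0.27), Cables1 (−0.25), Mkrn3 (−0.32), 5031439G07Rik (−0.38), Fam133b (−0.25), Edrf1 (−0.28) and the ceramide synthase Cers6 (−0.34). AY074887 was 0.79 but −0.66 with another background correction and −1.79 for its other probe, and the other probes of Sfmbt1 and Dok7 were at −0.03 and −0.07.

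In females limma called 0 genes, the smallest adjusted p was 0.832, and 854 genes had an unadjusted p under 0.05, 583 higher and 271 lower, where chance gives 1278. Groups did not overlap for 11.6% of genes, where chance gives 10%. Without BPA female replicate 2 there were 2 calls, both lower: Vps4a and a transcript region on chromosome 18, named only after their values were seen. The count at an unadjusted p under 0.05 was 537 without control female replicate 1 and 1517 without control female replicate 3. Leaving out BPA male replicate 3, which enters only through the shared estimate of spread, gave 1462.

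Striatal neuron markers were higher in exposed females, against the direction in males, with a median of 0.38 (18 of 18 higher, adjusted p 2.59e-12; adjusted p = 0.555 with an estimated correlation). The dopamine receptor Drd1 was at 0.40 (SE 0.11), the enkephalin precursor Penk at 0.49 (SE 0.13), Rgs9 at 0.66 (SE 0.21) and Adcy5 at 0.34 (SE 0.10). Interferon response and inflammation genes were lower, at −0.18 (16 of 22, adjusted p 1.83e-06; adjusted p = 0.555 with an estimated correlation), with Usp18 at −0.57, Irf9 at −0.30 and Bst2 at −0.29; the median was −0.11 with normexp. Meningeal and fibroblast markers were higher, at 0.24 (17 of 18, adjusted p 1.69e-06; adjusted p = 0.781 with an estimated correlation), with the proteoglycan Bgn at 0.37 and the anion transporter Slc22a6 at 0.35. Endothelial and pericyte markers were at 0.11 (17 of 22 higher, adjusted p 0.00334; adjusted p = 0.555 with an estimated correlation). Meningeal markers did not pass without control female replicate 3 (median 0.09, adjusted p 0.225), nor endothelial markers without BPA female replicate 3 (median 0.05, 0.270).

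The erythrocyte list was lower in females too, at −0.62 (8 of 11, adjusted p 0.000281), with Alas2 at −0.78 and Hba-a2 at −0.62. It had an adjusted p = 0.781 with an estimated correlation, and a median of −0.36 with normexp. Immediate early genes, which neurons switch on with activity, were at −0.25 (25 of 28 lower, adjusted p 0.00262; adjusted p = 0.781 with an estimated correlation), with Jun at −0.35. Glucocorticoid-responsive genes were at −0.17 (15 of 18 lower, adjusted p 0.00334), with Tsc22d3 at −0.26 and Nfkbia at −0.24, and heat shock and unfolded protein response genes at −0.05 (18 of 23 lower, adjusted p 0.0152), among them Atf3 at −1.43 (SE 0.79). These lists too had an adjusted p = 0.781 with an estimated correlation, and fry passed 0 lists in females. Immediate early genes had a median of −0.05 (adjusted p 0.270) without control female replicate 1, −0.03 (0.564) without control female replicate 2 and −0.01 (0.584) without BPA female replicate 3, but −0.68 without control female replicate 3. Glucocorticoid-responsive genes were at −0.08 (0.335) without control female replicate 2. Heat shock genes were at −0.00185 (0.564) without control female replicate 2, −0.03 (0.106) without BPA female replicate 1 and −0.02 (0.336) without BPA female replicate 3. With a single array left out, the median reached −0.12 for heat shock genes and −0.28 for glucocorticoid-responsive genes. Over all genes 0 list members passed, and 6 did when adjusted over the list alone: Drd1, Penk, Adcy5, Rgs9, Cldn5 and Ifit3.

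Averaging the sexes asked which genes differ in the mean of the male and female effects, with 6 arrays on each side. Those 6 arrays came from 3 dams, and littermates were treated as separate animals. The standard errors and p-values of this comparison therefore take no account of litter. A difference mainly in a single sex can also move that mean, so the comparison does not test sharing. On the higher side Dph7 was at 0.36 (SE 0.05), Abcg1, which exports cholesterol from cells, at 0.33 (SE 0.05) and Scg3 at 0.23 (SE 0.04). Also higher were Arfgap2, a regulator of Golgi vesicle coats, at 0.30 (SE 0.04), Osbpl9 0.33 (SE 0.05), Zbtb24 0.29 (SE 0.04), Dapl1 0.74 (SE 0.11) and Gm7276 0.49 (SE 0.08). On the lower side were Gnb4 at −0.27 (SE 0.04) and Tet1 at −0.30 (SE 0.05). None passed, with an adjusted p of 0.136 for each of these 10. Further down were Ifit3 at −0.50 (adjusted p 0.150), Laptm5 at −0.36 (0.152), Plcb1 at −0.29 (0.174), the DNA methyltransferase Dnmt3a at −0.24 (0.187), the splicing factor Srsf11 at −0.31 (0.187), whose other 2 probes were at 0.00 and 0.04, and Hmgb1 at −0.23 (0.190). The calls of this comparison turn on the processing: limma called 0 genes in the main setting and up to 67 in others, 64 of them higher, and Abcg1, Arfgap2, Dph7, Scg3 and Gnb4 passed in 5 of 26 other settings, with adjusted p from 0.0247 to 0.571 over their alternatives.

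**Figure D2:**
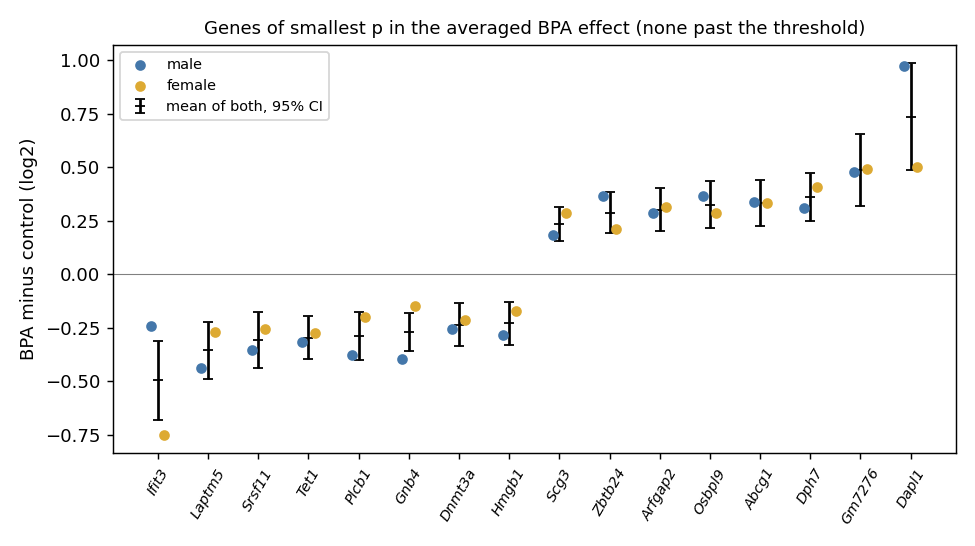
BPA minus control on the log2 scale for the 16 genes of smallest p in the averaged comparison, with the male (blue) and female (yellow) differences as points and their mean with its 95% confidence interval in black. The means run from −0.50 for Ifit3 to 0.74 for Dapl1, males and females lie on the same side of 0 for every gene shown, which is how the genes were chosen, and none passed.

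At an unadjusted p under 0.05 there were 2235 genes in the averaged comparison, 1583 higher and 652 lower, where chance gives 1278. Without BPA male replicate 1 there was 1 call, LOC634780, and without control male replicate 1 there was 1 call, a transcript region on chromosome 1, both higher and again named after their values were seen. Across genes, which are not independent replicates, the male and female differences correlated with Pearson's r of 0.01 and Spearman's rho of 0.13, and 57.7% had the same sign. Leaving out BPA male replicate 3 gave 0.26, 0.31 and 63.0%. The sexes share no array in this correlation but share the slides and the dams, so a slide or litter difference would raise it.

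Erythrocyte genes were lower in the averaged comparison, with a median of −0.70 (10 of 11, adjusted p 1.37e-07; adjusted p = 0.707 with an estimated correlation): Alas2 was at −0.89, Hba-a2 at −0.70, Hbb-b2 at −0.79 and Hbb-bt at −0.80. This median was −0.37 with normexp. Meningeal and fibroblast markers were higher, at 0.25 (17 of 18, adjusted p 0.000131; adjusted p = 0.707 with an estimated correlation), with Bgn at 0.40, Mgp at 0.37 and the matrix protein Fn1 at 0.27. Immediate early genes were at −0.33 (24 of 28 lower) and cholesterol and lipid synthesis genes at −0.11 (18 of 24 lower), each with an adjusted p of 0.000131 and an adjusted p = 0.707 with an estimated correlation. Interferon response and inflammation genes were at −0.07 (14 of 22 lower, adjusted p 0.00152; adjusted p = 0.707 with an estimated correlation), with Isg15 at −0.35, Usp18 at −0.38 and Bst2 at −0.27; the median was −0.13 after quantile normalisation.

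Small shifts were seen for heat shock and unfolded protein response genes, at −0.06 (17 of 23 lower, adjusted p 0.00450; adjusted p = 0.707 with an estimated correlation). Oxidative phosphorylation genes (27 of 36 lower) and cytosolic ribosomal proteins (26 of 38 lower) were each at −0.03, with an adjusted p of 0.00626 and an adjusted p = 0.774 with an estimated correlation. Without BPA male replicate 3 those 3 lists had adjusted p of 0.390, 0.646 and 0.473, and they did not pass after quantile normalisation or with normexp, while the other 5 passed with any single array left out. Their medians moved all the same: interferon genes were at −0.01 without control male replicate 2, cholesterol genes at −0.04 without BPA male replicate 2, immediate early genes at −0.18 without BPA female replicate 3 and meningeal markers at 0.13 without control female replicate 3. Immediate early genes did not pass (adjusted p 0.119) without both BPA male replicate 3 and control female replicate 1. Heat shock genes also had an adjusted p of 0.0683 without control male replicate 3 and 0.0789 without control female replicate 2. For oxidative phosphorylation it was 0.0628 and 0.0789, and for ribosomal proteins 0.168 without control male replicate 2. With a single array left out, the heat shock median ran from −0.11 to −0.03. In this comparison fry passed 0 lists. Over all genes 0 list members passed, and 18 did when adjusted over the list alone, among them Tet1, Dnmt3a, Mbd1 (0.20) and Dnmt1 (0.18).

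**Figure D3:**
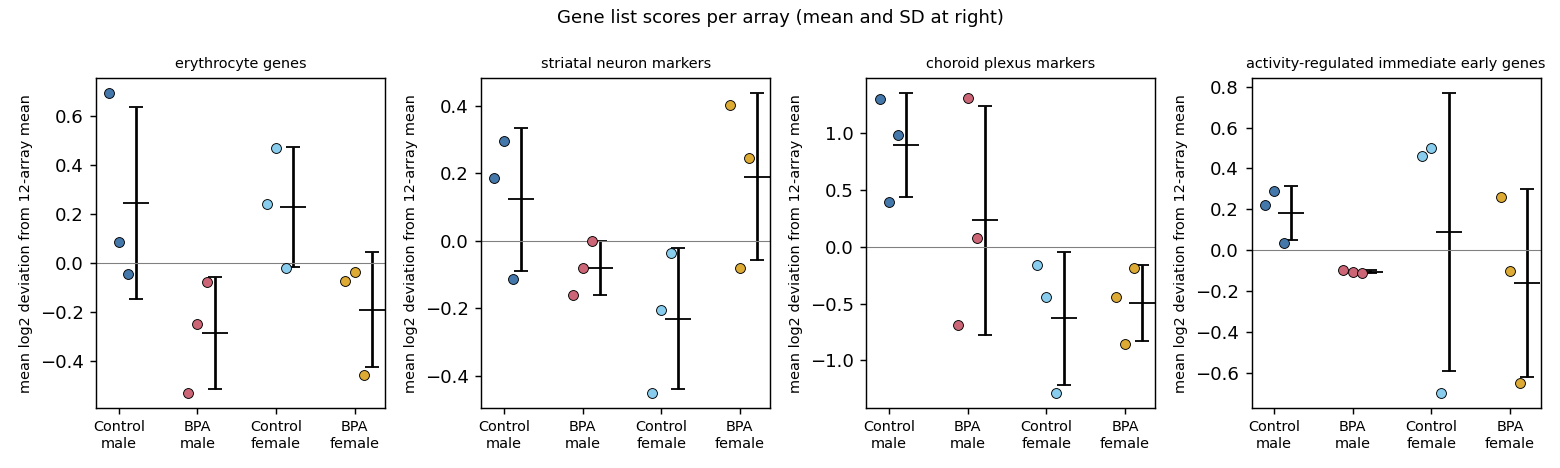
Mean log2 deviation of the members of 4 gene lists from their 12-array mean, 1 point per array, with the mean and SD (n = 3) at the right of each group. Erythrocyte scores averaged 0.25 in control males, −0.29 in BPA males, 0.23 in control females and −0.19 in BPA females, and choroid plexus scores spread most within BPA males (SD 1.01).

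Estrogen receptors were examined because BPA can bind estrogen receptors. Esr1, estrogen receptor alpha, was 0.31 higher in exposed males (95% confidence interval −0.14 to 0.76) and 0.12 in exposed females (−0.33 to 0.57). Esr2, estrogen receptor beta, was −0.13 in males (−0.33 to 0.08) and −0.15 in females (−0.35 to 0.05). Averaged over the sexes the adjusted p was 0.690 for Esr1 and 0.587 for Esr2, so neither passed. Differences in males were −0.02 for Esrra, 0.15 for Esrrb, 0.09 for Esrrg, 0.02 for the membrane estrogen receptor Gper1, −0.04 for Ahr, −0.02 for Thra and 0.00 for Thrb. The list of nuclear receptors and coregulators (29 measured) had medians of −0.02 in males (adjusted p 0.564) and 0.04 in females (0.453). Estrogen-responsive genes (19 measured) had medians of 0.04 in males (0.756) and 0.02 in females (0.804). Their mean score per array was −0.14 ± 0.03 in control and 0.15 ± 0.17 in exposed males (mean ± SD, n = 3), without overlap, though the list did not pass. Named after their values were seen, the neuropeptides Oxt at 2.68 (adjusted p 0.524) and Avp at 1.45 (0.575) had the largest differences in it, and neither passed. Both are also members of the thalamic and hypothalamic neuron markers, a list whose score lay the same way without overlap. That score was at −0.29 ± 0.20 in control and 0.22 ± 0.24 in exposed males (median difference 0.19, adjusted p 0.217, not passing). The shared members enter both scores, so the likeness is partly built in. Scores of erythrocyte, oligodendrocyte and immediate early genes did not overlap between these groups either. With 3 arrays against 3, such a separation can also arise by chance. In the averaged comparison, steroid synthesis genes were at 0.05 (adjusted p 0.965), thyroid hormone genes at 0.01 (0.965), dopamine, serotonin and noradrenaline genes at 0.04 (0.964) and DNA methylation and histone-modifying enzymes at −0.02 (0.142).

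Whether the BPA effect differs between the sexes was tested as an interaction, the female effect minus the male effect. On the positive side Cldn5 was at 0.45 (SE 0.11), Gnal, a G protein that couples dopamine receptors to adenylate cyclase, at 0.39 (SE 0.10) and Adcy5, the adenylate cyclase of striatal neurons, at 0.54 (SE 0.14). Drd1 was at 0.56 (SE 0.15), Taf15 at 0.50 (SE 0.14) and Tasor at 0.32 (SE 0.09). On the negative side Baz1a was at −0.61 (SE 0.16), Gm12059 at −0.72 and Zfp141 at −0.61. Ftdc1 and 4930470P17Rik were also among the genes of smallest p, but no value is given, since their probes were not well above background on any BPA female array, nor, for the latter, on any control male array. Yy2 was at −0.87 but at 0.40 after quantile normalisation, and Zfp141 turned to 0.17. None passed, with an adjusted p of 1.00 for each.

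For the interaction limma called 0 genes, in the main setting and in every alternative, and 600 genes had an unadjusted p under 0.05, 159 higher and 441 lower, where chance gives 1278. That count was 1687 without BPA male replicate 1, 1051 without BPA male replicate 2, 391 without BPA female replicate 3, 348 without control female replicate 1 and 951 without control female replicate 3. The camera test passed 13 lists, 11 positive and 2 negative, each lost its call with an estimated correlation, and fry passed 0. Striatal neuron markers had a median of 0.59 (18 of 18 positive, adjusted p 3.79e-19; adjusted p = 0.381 with an estimated correlation), with Penk at 0.67 and Rgs9 at 0.98. Interferon response and inflammation genes were at −0.26 (adjusted p 0.0116; adjusted p = 0.579 with an estimated correlation), with Ifit3 at −0.51. Its adjusted p was 0.124 without control male replicate 1, 0.122 without control male replicate 3 and 0.0980 without BPA female replicate 3, and its median was −0.06 after quantile normalisation, −0.12 with normexp and −0.15 without BPA female replicate 3. Oligodendrocyte and myelin markers were at 0.22, with Ugt8a at 0.48 (adjusted p 2.82e-07; adjusted p = 0.579 with an estimated correlation). Over all genes 0 list members passed, and 6 did when adjusted over the list alone, among them Adcy5, Drd1, Penk, Rgs9 and Rasd2 (0.60).

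The comparison of control females with control males asked which genes differ between the sexes without exposure, and it checks the sex labels. Xist, the RNA that silences an X chromosome in females (chromosome X, 100656289 to 100656348), was at least 91.7-fold higher in females (adjusted p 2.78e-08), at 0.93 ± 0.05 against −7.88 ± 0.10 in males (log2 relative to the 75th percentile, mean ± SD, n = 3, limma). A neighbouring probe that the array design labels XIST differed by 11.52 (SE 0.67, adjusted p 7.08e-05), with 1 of the 3 control male arrays well above background. Among Y-linked genes, males were at least 228-fold higher for the translation factor Eif2s3y (adjusted p 3.66e-06) and 98.5-fold for the helicase Ddx3y (8.51e-11). In the same class they were at least 4.87-fold higher for Uty (2.05e-07) and 8.17-fold for LOC100040412 (0.00584). B830012L14Rik (chromosome 12, 110934160 to 110934219) was 1.16 higher in females (SE 0.14, adjusted p 0.0375), and it passed in 10 of 26 alternatives, with adjusted p from 0.00666 to 1. Kdm5d was at −2.04 and did not pass (adjusted p 1.00). Xist and the Y-linked genes matched the labelled sex on all 12 arrays.

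**Figure D4:**
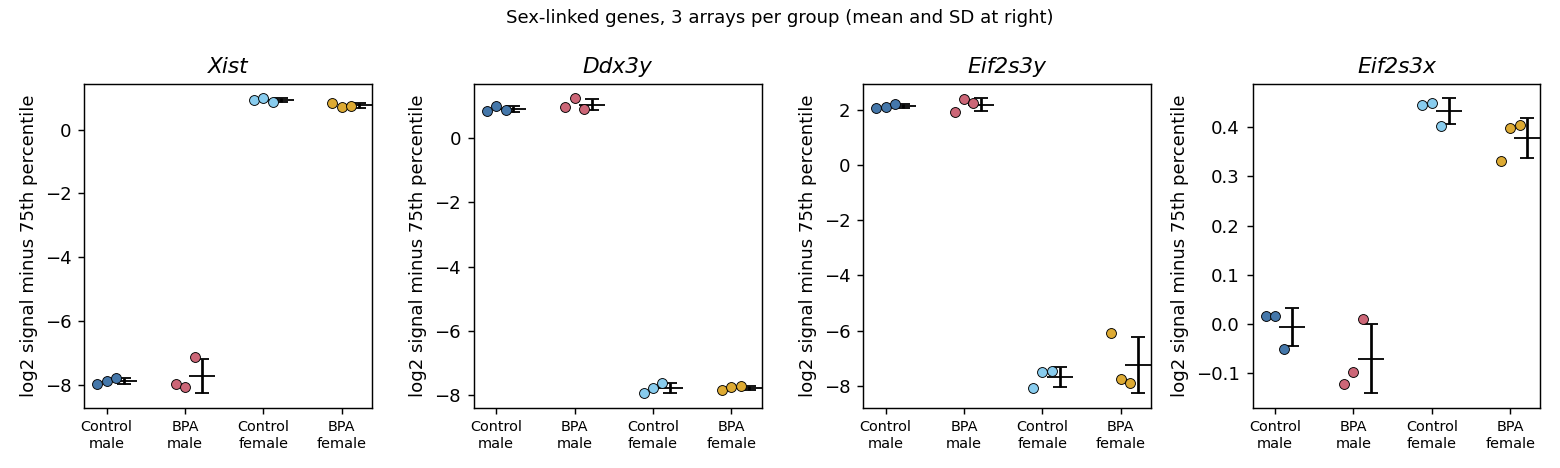
Log2 signal relative to the 75th percentile of each array for Xist, the Y-linked Ddx3y and Eif2s3y, and the X-linked Eif2s3x, 1 point per array, with the mean and SD (n = 3) at the right of each group. Xist averaged 0.93 in control females and −7.88 in control males, and Ddx3y 0.92 in control males and −7.79 in control females.

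In controls limma called 7 genes, 3 higher and 4 lower in females, and 381 genes had an unadjusted p under 0.05, where chance gives 1278. The latter count was 642 without control male replicate 3, 1128 without control female replicate 3 and 751 without BPA male replicate 3. Groups did not overlap for 5.43% of genes, where chance gives 10%. X-linked genes that escape inactivation were higher in females, with a median of 0.36 (9 of 9, adjusted p 3.66e-35; adjusted p = 3.98e-05 with an estimated correlation), and also passed fry (adjusted p 5.68e-09). The histone demethylase Kdm6a was at 0.36, 5530601H04Rik at 0.50 and Eif2s3x at 0.44, the last with an adjusted p of 0.050001, just above the threshold (0.0184 to 1.00 over its alternatives). The only other Eif2s3x probe went the other way, at −2.47. Xist is itself a member of the escape list and adds to its passes, and the list was not tested without it. Choroid plexus markers were lower in control females, at −1.31 (15 of 15, adjusted p 1.43e-23; adjusted p = 0.162 with an estimated correlation), with Kcne2 at −3.05 (SE 0.86), Folr1 at −2.22 (SE 0.62), Kl at −1.63 (SE 0.47) and Sostdc1 at −1.31 (SE 0.42); the median was −0.72 with normexp. Striatal neuron markers were lower, at −0.32 (17 of 18, adjusted p 1.86e-13; adjusted p = 0.284 with an estimated correlation), with Adcy5 at −0.33 and Drd1 at −0.29. Interferon response and inflammation genes were higher, with a median of 0.17 (21 of 22, adjusted p 5.13e-08; adjusted p = 0.284 with an estimated correlation), and so were heat shock and unfolded protein response genes, at 0.14 (21 of 23, adjusted p 1.03e-08; adjusted p = 0.284 with an estimated correlation). The interferon median was 0.08 with normexp and 0.28 without control male replicate 2, and the heat shock median 0.25 without control female replicate 1 and 0.09 without control female replicate 3.

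Hippocampal neuron markers were lower in control females, at −0.11 (adjusted p 0.000284; adjusted p = 0.284 with an estimated correlation), with Lct at −0.68. Oligodendrocyte and myelin markers were at −0.10 (adjusted p 0.00261; adjusted p = 0.817 with an estimated correlation) and microglia and macrophage markers at −0.06 (adjusted p 0.00251; adjusted p = 0.517 with an estimated correlation). Glucocorticoid-responsive genes were higher, at 0.15 (adjusted p 0.00251; adjusted p = 0.590 with an estimated correlation). Each of these 4 lists lost its call without some arrays. Oligodendrocyte markers had a median of −0.07 (adjusted p 0.184) without control male replicate 2, −0.03 (0.766) without control female replicate 1 and −0.03 (0.519) without control female replicate 2, but −0.23 without control female replicate 3. Microglia markers were at −0.02 (0.553) and −0.05 (0.0817) without the first 2 of these, and at −0.11 without control female replicate 3. With normexp neither list passed (0.0535 and 0.0687). Hippocampal markers were at −0.05 (0.172) without control male replicate 1 and −0.14 (0.136) without control female replicate 3, but at −0.24 without control male replicate 2. Glucocorticoid-responsive genes were at 0.08 (0.248) without control male replicate 1, 0.08 (0.0607) without control female replicate 1 and −0.000354 (0.503) without control female replicate 2. Over all genes 1 list member passed, Xist, and 19 did when adjusted over the list alone.

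Sex was compared again among exposed animals, which asked whether the same differences appear under BPA. The same sex-linked genes led: females were at least 80.3-fold higher for Xist (adjusted p 3.95e-08), and males at least 240-fold for Eif2s3y (5.32e-06), 110-fold for Ddx3y (7.39e-11), 4.90-fold for Uty (2.35e-07) and 9.87-fold for LOC100040412 (0.00115). The XIST-labelled probe differed by 8.46 (adjusted p 0.00115), and it was well above background on every BPA male and every BPA female array. Eif2s3x, the X-linked partner of Eif2s3y (chromosome X, 91435083 to 91435142), was 0.45 higher in females (SE 0.06, adjusted p 0.0480); it passed in 8 of 26 alternatives, with adjusted p from 0.00749 to 0.889. The gene's only other probe went the other way, at −2.61. Kdm5d was at −2.40 and did not pass (adjusted p 0.451). In this comparison limma called 7 genes, 3 higher and 4 lower, and 1286 genes had an unadjusted p under 0.05, where chance gives 1278. Groups did not overlap for 9.77% of genes, where chance gives 10%. The count at an unadjusted p under 0.05 was 736 without BPA male replicate 3, 3391 and 2388 without BPA male replicates 1 and 2, and 835 and 791 without BPA female replicates 2 and 3.

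Escape genes were again higher in exposed females, at 0.31 (9 of 9, adjusted p 9.78e-20; adjusted p = 0.000359 with an estimated correlation), with 5530601H04Rik at 0.34 and Kdm6a at 0.32. Camera passed 16 lists, 14 higher and 2 lower, of which only the escape genes, Xist included, held with an estimated correlation or in fry. The other 15 had an adjusted p = 0.470 to 0.536 with an estimated correlation. Striatal neuron markers were higher, at 0.25 (18 of 18, adjusted p 8.42e-09; adjusted p = 0.470 with an estimated correlation), with Rgs9 at 0.52, Penk at 0.36 and Drd1 at 0.27. Choroid plexus markers were lower, at −0.61 (15 of 15, adjusted p 0.00435; adjusted p = 0.536 with an estimated correlation). Glucocorticoid-responsive genes were lower, at −0.22 (17 of 18, adjusted p 0.00899), with Nfkbia at −0.37. Medians on the higher side were 0.12 for oligodendrocyte and myelin markers (8.18e-05), 0.09 for cholesterol and lipid synthesis (3.43e-05), 0.10 for meningeal and fibroblast markers (0.00679), 0.09 for erythrocyte genes (0.0188) and 0.07 for heat shock genes (1.88e-05). Without BPA male replicate 2 choroid plexus markers were at −0.12 (adjusted p 0.950), glucocorticoid-responsive genes at −0.08 (0.681) and cholesterol and lipid synthesis genes at 0.02 (0.200). Erythrocyte genes had an adjusted p of 0.183 without BPA male replicate 1, 0.0999 without BPA female replicate 1 and 0.127 without BPA female replicate 2. With single arrays left out the medians ran from 0.06 to 0.21 for erythrocyte genes (lowest without BPA male replicate 1, highest without BPA male replicate 3), and to 0.17 for heat shock genes without BPA male replicate 1. They ran from 0.07 without BPA female replicate 3 for oligodendrocyte markers, and from 0.16 to 0.39 for striatal markers (without BPA female replicates 1 and 2). After quantile normalisation 5 of the 16 lists passed, those of escape, striatal, glucocorticoid, heat shock and choroid plexus genes, with choroid plexus markers at −0.32; that median was −1.10 without BPA male replicate 1.

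Of these 16 lists, 9 passed without BPA male replicate 3. Those that did not were microglia and macrophage markers (median 0.06, adjusted p 0.00435, and 0.0623 without that array), oxidative stress and NRF2 genes (0.05, 0.00523 and 0.191), oxidative phosphorylation (0.04, 0.000127 and 0.969), GABA genes (0.03, 0.00911 and 0.573), synaptic proteins (0.03, 0.0212 and 0.892), Notch pathway genes (0.04, 0.0388 and 0.0597) and imprinted genes (0.03, 0.0188 and 0.573). The median turned negative without that array for synaptic proteins (−0.03), imprinted genes (−0.02), oxidative phosphorylation (−0.01) and GABA genes (−0.00334). With other arrays left out, the synaptic list was at 0.144 without BPA female replicate 2 and 0.103 without BPA female replicate 3. The Notch list was at 0.0545 without control male replicate 2, 0.165 without BPA male replicate 1 (median −0.00227) and 0.141 without BPA female replicate 1. For imprinted genes the mean was −0.00, so the mean differed in sign from the median and the test. Over all genes 2 list members passed, Xist and Eif2s3x, and 6 did when adjusted over the list alone. The median, the mean and the test's direction were not all of 1 sign for 15 of 38 lists in males, 5 in females, 7 in the averaged comparison, 10 in the interaction, 7 in control sexes and 18 in exposed sexes, and imprinted genes were the only such list that passed. Of the 38 lists, 17 passed in no comparison.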

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

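The tests of dim probes, spike-ins, negative controls, the left-out array and list correlations were chosen only after the result was seen; the splits and the interaction were planned. Arrays were screened within each treatment, 6 at a time, for 1 array far from the other 5. Of 18 such sets, 6 had one, where chance gives about 1 in 20.

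In BPA male replicate 3, 90.5% of spots were well above background, against 65.1% to 68.1% on the other BPA arrays. Its median signal was 96.4 units against 46.8 to 53.3, the net signal of its negative controls 32.3 against 22.3 to 24.8, and its spike-in slope 0.992 against 0.882 to 0.905. Control female replicate 1 stood out less: 73.5% of spots were well above background against 64.7% to 67.1% on the other control arrays, with a median signal of 56.6 against 43.1 to 46.6.

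The raise on BPA male replicate 3 lies in dim probes. An even background left in the processed signal is argued against: on that signal, which is not the net signal given above, negative control probes rose by 1.65 units, 6.93% of the 23.8 units by which dim mouse probes rose. More transcripts in this animal's RNA as the whole cause is argued against too. The dimmest spike-in, added at a fixed amount, was 9.37 times the highest of the other arrays (41.3 against 4.41 units). The next brighter spike-ins were at 7.54, 1.72 and 1.23 times the highest other array. The 6 brightest lay within the range of the other arrays, at 0.902 to 0.951 times the highest. A candidate explanation is cross-hybridisation that depends on sequence, since the dimmest spike-in was raised though it is no mouse transcript. The raise also grew with the GC content of 12901 dim probes (r = 0.433 across probes). A biological difference of this animal beside that stays open, as untested.

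The averaged BPA comparison had 2235 genes at an unadjusted p under 0.05, where chance gives 1278. BPA male replicate 3 as the whole cause is argued against, since 2728 genes had such a p without it. Exposure and slide cannot be told apart, because 0 slides hold both treatments, so a difference between slides could give the same excess. The arrays of a treatment came from 3 dams and were treated as separate animals, so the count takes no account of litter either. Of 100 splits of the arrays, the real one included, 6 gave as many genes at that p. The highest other was 2857, so chance cannot be excluded. The other splits regrouped males and females separately, so they mixed the slides, which the real grouping does not. The 6 is therefore not a plain measure of chance. With 0 genes past the adjusted threshold and at most 3 in another split, all 100 give as many by construction, which tests nothing.

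Under the preset correlation erythrocyte genes were lower in exposed animals of both sexes, and striatal and choroid plexus markers differed by sex in controls; each call was lost, with an adjusted p = 0.651 with an estimated correlation in males, 0.781 in females, 0.284 for striatal and 0.162 for choroid plexus markers. Pieces of cortex that carried differing amounts of blood, striatum or choroid plexus are a candidate explanation: within groups the members of a list moved together, with a mean correlation of 0.430 for erythrocyte genes, 0.476 for striatal markers and 0.650 for choroid plexus markers, above the 95th percentile of 1000 random lists of like signal (0.0827, 0.0872 and 0.252). Genes under 1 control would move together as well, so this test does not part the tissue explanation from a biological one. The tissue candidate applies equally to the striatal difference in exposed females and to the striatal and choroid plexus differences in the interaction, where the same control arrays enter. An effect of BPA or sex on these cells stays open, as untested.

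The BPA effect differed by sex for 13 gene lists in the interaction test with a preset correlation, female minus male effect. None held with an estimated correlation: the adjusted p = 0.381 with an estimated correlation for striatal markers, 0.619 for ribosomal proteins and 0.579 for each of the other 11. The medians were 0.59 for striatal neuron markers (adjusted p 3.79e-19), 0.22 for oligodendrocyte and myelin markers (2.82e-07), 0.58 for choroid plexus markers (0.000105), 0.14 for cholesterol and lipid synthesis (0.000138) and 0.10 for microglia and macrophage markers (1.98e-05). Smaller ones were 0.14 for erythrocyte genes (0.0478), 0.0463 for endothelial and pericyte markers (0.0187), 0.0498 for synaptic proteins (0.0221), 0.0568 for oxidative stress and NRF2 genes (0.0242), 0.0323 for oxidative phosphorylation (0.00118) and 0.0284 for ribosomal proteins (0.0210), the last turning to −0.00276 after quantile normalisation and −0.00452 without BPA male replicate 3. Medians also turned for erythrocyte genes, to −0.02 without control male replicate 1, and, without both BPA male replicate 3 and control female replicate 1, for synaptic proteins (−0.01) and oxidative phosphorylation (−0.02). Negative medians were −0.28 for glucocorticoid-responsive genes (4.58e-05) and −0.26 for interferon response and inflammation genes (0.0116). Under the preset correlation 8 of the 13 passed without BPA male replicate 3; the erythrocyte, synaptic, oxidative stress, oxidative phosphorylation and ribosomal lists did not. Only the oligodendrocyte, microglia, striatal and glucocorticoid lists, 4 of 13, passed with each array left out in turn, and their medians moved: to 0.04 and 0.15 for microglia markers without control male replicates 2 and 3, and to −0.45 for glucocorticoid-responsive genes and 0.33 for oligodendrocyte markers without control female replicate 3. Choroid plexus markers missed without BPA male replicate 1 (median 0.20, adjusted p 0.112) and were at 0.97 without BPA male replicate 2, where cholesterol and lipid synthesis missed (0.05, 0.101). Endothelial markers missed without BPA female replicate 3 (0.0111, 0.160), BPA male replicate 1 (0.0365, 0.0866) and control female replicate 2 (0.0718, 0.0525). After quantile normalisation 6 of the 13 passed, and cholesterol (0.0851) and endothelial markers (0.205) were among those that did not; normexp passed 9. Interferon genes missed without each of 3 arrays (0.0980 to 0.124).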

How the results depend on the processing

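Tests with bright genes alone, with or without BPA male replicate 3, and with both outlying arrays left out were chosen only after the result was seen; the others were planned. No result changed sign and stayed past its threshold. In males, in females and in the interaction limma called 0 genes in every alternative other than leaving out 1 array. In the averaged comparison it called 0 in the main setting and in 8 of 14 alternatives, but 67 with normexp (64 higher, 3 lower), 2 with every probe by itself (2 higher, both in transcript regions without a symbol), 18 with trend and robust (13 higher, 5 lower), 23 with array weights (21 higher, 2 lower), 16 with bright genes (12 higher, 4 lower) and 34 with bright genes without BPA male replicate 3 (29 higher, 5 lower). Over all 26 alternatives, with single arrays left out among them, 8 genes passed in 5 settings, 5 in 4, 13 in 3, 10 in 2 and 43 in 1; the 8 were Abcg1, Arfgap2, Dph7, Scg3, Gnb4, Eif4enif1, Sfmbt1 and a transcript without a symbol. The cause of these differences was not tested.

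Sex differences gave 7 calls each. Requiring signal on all 12 arrays gave 0 in controls and 0 in exposed animals (357 and 1069 genes at an unadjusted p under 0.05): Xist and Y-linked genes, dim in 1 sex, drop out by construction, while B830012L14Rik and Eif2s3x were tested and missed (adjusted p 0.166 in controls and 0.277 in exposed animals). Every probe by itself gave 15 and 15, bright genes 3 and 2, and bright genes without BPA male replicate 3 gave 3 and 2. Xist, Ddx3y, Eif2s3y and Uty passed in all 23 alternatives that tested them, in controls and in exposed animals. LOC100040412 missed in 4 of 23 in controls (adjusted p up to 0.594) and 1 of 23 in exposed animals (up to 0.181), and the XIST probe in 1 of 24 in exposed animals (0.0969; the range was 1.69e-10 to 0.0969).

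Lists passing were 12 in males, 8 in females, 8 averaged, 13 in the interaction, 9 in control sexes and 16 in exposed sexes. With an estimated correlation, and with fry, they were 0, 0, 0, 0, 1 and 1. Quantile normalisation gave 7 in males, 5 averaged, 6 in the interaction and 5 in exposed sexes; normexp gave 5 averaged; bright genes gave 5 averaged, 7 in the interaction and 6 in exposed sexes; and leaving out both outlying arrays gave 9 in exposed sexes. The cause was not tested.

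Leaving out 1 array at a time gave 0 to 1 gene in males, 0 to 2 in females, 0 to 1 averaged, 0 to 0 in the interaction, 5 to 7 in control sexes and 6 to 8 in exposed sexes. Lists ranged over 8 to 14, 5 to 13, 5 to 14, 8 to 17, 6 to 15 and 9 to 17. Without control female replicate 3 there were 13 lists in females, 14 averaged and 15 in control sexes; without control male replicate 3, 14 in control sexes; without BPA female replicate 3, 5 in females; and without BPA male replicate 3, 5 averaged, 8 in the interaction and 9 in exposed sexes. Every such fit passed 4 of the 12 lists in males (oligodendrocyte, erythrocyte, striatal and cholesterol), 3 of 8 in females (erythrocyte, striatal and interferon), 5 of 8 averaged (immediate early, meningeal, erythrocyte, interferon and cholesterol), 4 of 13 in the interaction, 5 of 9 in control sexes and 5 of 16 in exposed sexes.

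The replicate number was tried as a block. Deviations of same-numbered males and females correlated with r of 0.01, 0.37 and 0.19 in controls and −0.16, 0.12 and 0.01 in exposed animals, and not every array correlated best with its own number, so the numbers were not read as pairs. The fixed block gave 4 calls in exposed sexes, and no other count moved by over 1.5 times. Without the filter on dim probes the median of all genes moved to 0.13 in males, −0.11 in the interaction and −0.14 in exposed sexes, from 0.04, −0.03 and −0.03. The estimated weight of BPA male replicate 3 was 0.163, against 0.671 to 1.95 for the other arrays. A slide block was not run for any result: 0 slides hold both treatments, and sex differences lie within a slide.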

Other observations

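The tests in this part, of lists and of other splits of the samples, were planned. The list of DNA methylation and histone-modifying enzymes did not pass in the averaged comparison (13 of 29 higher, 16 lower, median −0.02, adjusted p 0.142). Tet1 was at −0.30 (SE 0.05) and the de novo methyltransferase Dnmt3a at −0.24 (SE 0.04), while the methyl-CpG reader Mbd1 was at 0.20 (SE 0.05) and the maintenance methyltransferase Dnmt1 at 0.18 (SE 0.05). These 4, named for their values, passed when adjusted over the list alone, which does not correct for the number of lists. They did not pass over all genes, where the adjusted p was 0.136, 0.187, 0.266 and 0.282. Interneuron markers had medians of 0.05 in males (adjusted p 0.492) and −0.04 in females (0.985), and Crh, a neuropeptide of some interneurons, was at 0.41 in the averaged comparison (adjusted p 0.187). Astrocyte markers had medians of −0.00 in males (adjusted p 0.645) and 0.08 in females (0.305).

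In males the real split gave 0 genes and the highest other 0, and in females 0 and 4; with a real count of 0 all 10 splits give as many by construction, which tests nothing. At an unadjusted p under 0.05 the real split gave 2190 genes in males (highest other 2412) and 854 in females (highest other 1351), and 3 of 10 splits gave as many in each sex. In control sexes the real split gave 7 genes and the highest other 228, so 2 of the 10 splits gave as many, and in exposed sexes the real split gave 7 and the highest other 0, so 1 of 10 did. With 10 splits, a share under 0.05 is out of reach. For the interaction, 84 of 100 splits gave as many genes at an unadjusted p under 0.05 as the real 600, the highest other being 2693, so chance cannot be excluded; past the adjusted threshold the real count was 0 and the highest other 3, and 100 of 100 give as many by construction.

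The 228-gene split set control male replicates 1 and 3 and female replicate 3 against male replicate 2 and female replicates 1 and 2. It was picked as the highest of 10 splits, so its count alone tests nothing. The second principal component (11.2% of the variance), drawn from the same values, parted these arrays alike. The first 3 were at 16.5 to 21.1 and the others at −32.2 to −17.4. On the slide the others held row 1, columns 2 to 4, and the first 3 held row 1, column 1 and row 2, columns 1 and 2. The cause was not tested.

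In the authors' processed table, control female replicate 1 and BPA male replicate 3 followed their scanner files with r of 0.224 and 0.218 across probes, against 0.959 to 0.978 for the other 10 arrays; across bright probes r was 0.791 and 0.404, against 0.976 to 0.991. Column medians were 0, 0.01 and 0.01 for control males, 0, −0.03 and 0.02 for control females, −0.02, −0.01 and 0.02 for BPA males and −0.01, 0 and 0 for BPA females. Across bright genes the male and female BPA differences correlated with r of 0.32, and with 0.42 without BPA male replicate 3. Here too the sexes share the slides and the dams.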
